A study of Mus musculus with 2 samples.

How the data were processed

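Single cells were measured with droplet-based 3' RNA sequencing (10x Genomics Chromium) after sorting mCherry-positive cells from mouse lung, per the labels' protocols. Reads were processed with Cell Ranger 3.0.2 and the mm10 genome, per the submitters' processing notes. The annotation, the filters on genes and cells and any removal of doublets are not given in the sources used here. The deposited values were natural-log values: the authors divided each gene's UMIs by the cell's total, multiplied by 10000, added 1 and took the natural log, as the values themselves show, since their back-transformed sum was 10000 in every cell. Every gene listed was detected in at least 3 cells, and the mitochondrial share was at most 5.00% of a cell's UMIs. The cell names carried 2 library numbers that match neither sample title, so both libraries were pooled into 1 sample and values per library are given as within-batch values. No column of cells was left unused.

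The back-transformed values of each cell were whole multiples of its smallest value, with a largest deviation of 1.78e-10, so whole UMIs per gene and cell were recovered and used for rates, intervals and thinning. A rate is the summed UMIs of a gene over the cells of a class per 10000 UMIs of those cells. Poisson intervals are exact, and shares of cells carry exact binomial (Clopper-Pearson) intervals at 95%; the limit for a count of 0 is 3 counts of the total. A rate weighted over clusters, used in the closing section, carries a normal interval from the Poisson variances. Cells are not independent animals, and UMIs of one gene vary more between cells than a Poisson law allows, so these intervals cover counting error only. Because shares of cells with a UMI depend on depth, the expected share after drawing 2500 UMIs from each cell was computed as well; the shallowest cell had 2517 UMIs.

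Cells were clustered with scanpy 1.11.5 on 2000 variable genes, from which the function lists and mCherry had been removed so that they could be compared between classes. Values were scaled and limited to 10, and 20 principal components, 15 neighbours and the Leiden method at a resolution of 0.5 (igraph 0.11.9) gave 13 clusters, numbered by size. Clusters were named from 27 marker lists fixed before the data were examined, by looking at detected markers and leading genes; a cluster whose leading genes went against a name stayed unnamed, which gave 11 classes with the 3 endothelial-like clusters joined. No doublets were removed. Cells with at least 3 markers of 2 or more of 7 unrelated lineages at 2 or more UMIs were counted (29 of 1344, 2.16%) and left out in an alternative.

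Between classes, each gene's mean natural-log value in a class was set against the unweighted mean of the other class means, among 12702 genes detected in at least 1% of cells. For the 10 function lists (senescence regulators, senescence-associated secretory factors, proliferation, p53 targets, lysosome, interferon response, antigen presentation, lipid handling, dissociation and stress response, iron and oxidative stress) the median difference was ranked among 10000 random lists drawn within 20 bins of mean level. Genes of a list vary together, so such percentiles are more extreme than for independent genes and are used as descriptions. Endothelial-like cells with and without a Cdkn2a UMI were matched within 10 bins of genes detected, and 7047 genes detected in at least 10% of cells on either side were compared. Since the matrix is 1 sample, no test across samples was run.

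Genes named in the text follow a rule fixed before the data were examined. From each function list up to 4 members with the largest difference, detected in at least 5% of cells of a class or of the others, could be named, with Cdkn2a, Cdkn2b, Cdkn1a, Mki67, Il6, Il1b and mCherry always, the 20 genes with the largest difference in the Cdkn2a comparison, and up to 5 leading genes of a cluster as its identity. Some genes that the rule covers are not reported here. Members whose UMI rate went against their natural-log difference were left out. Scgb1a1, the leading gene of cluster 10, was chosen as a gauge of free RNA after its values were seen. Igkc, named for its share of UMIs, was also chosen afterwards. Rates without the cell holding most UMIs of a gene were computed afterwards too and are given where the rate moved by over 1.5 times. Gene positions come from the GENCODE mouse annotation of GRCm38 (release M, number 21), which held 15363 of the 15526 gene symbols (99.0%).

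Alternatives fixed in advance were another clustering resolution, variable genes with the function lists kept, 30 components, filters on genes per cell, removal of cells with markers of several lineages, pseudocounts of 0.1 and 1 on linear means, other filters on low genes, and other matchings of the Cdkn2a comparison. Each library alone, thinning, leaving out cluster 10 and matching within cluster and library were added after seeing the data. The steps were tested on simulated Poisson counts with the real gene means and cell totals. For the comparison of endothelial-like cells with the other classes, over 13063 genes, 2-fold changes were recovered with a median ratio of 2.01 and 0.5-fold changes with 0.518, with the right direction in 100% of both. Of 100 lists of unchanged genes in that simulation, 4 fell outside the central range. For the Cdkn2a comparison, endothelial-like cells were labelled at random in counts without cluster or library differences. Over 7330 genes, the 20 genes with the largest difference were then all among the 135 changed ones. This does not show how the real comparison fares, since its 2 sides differed in clusters and libraries.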

Results

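Lung cells carrying a p16 reporter were profiled one by one in old mice. The mice were p16-FDR animals on the C57BL/6 background, whose reporter allele joins an FLP recombinase with a diphtheria toxin receptor fused to the red fluorescent protein mCherry. p16 is a cyclin-dependent kinase inhibitor encoded by Cdkn2a and is widely used as a marker of cellular senescence. The labels give 1 group, mCherry-positive cells sorted from the lungs of mice aged 20 to 22 months, with 2 samples. The table held 1344 cells and 15526 genes, in which library 1 gave 1145 cells and library 2 gave 199 cells. Library 1 had a median of 5631 unique molecular identifiers (UMIs) per cell (range 2517 to 49467) and library 2 a median of 6716 (range 2526 to 41631). Which library belonged to which sample could not be told from the cell names, so the table was treated as 1 sample. No test was run, and comparisons are between cell classes within the sorted population. Intervals are 95% exact binomial intervals for shares and 95% exact Poisson intervals for UMI rates, and both cover counting error only. Sorted cells without mCherry were not analysed here, so no background level from a negative gate stands beside these values.

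The first question was which cell types made up the reporter-positive population. Endothelial-like cells were the largest class, with 604 cells or 44.9% of the total (42.3 to 47.6%). They formed 3 clusters, led by Car4, Kdr, Pcdh1, Prx and Cyp4b1 in cluster 1, by Ptprb, Plvap, Edn1, Vwf and Gja4 in cluster 3, and by genes including Pcdh12 and Mfng in cluster 9. T-cell-like cells followed with 156 cells (11.6%, 9.94 to 13.4%), then interstitial-macrophage-like cells with 116 (8.63%, 7.18 to 10.3%), which were led by Ccl8, Cd209f, F13a1, Folr2 and Cd163. Fibroblast-like cells, led by Apod, Mmp3, Inmt, Limch1 and Gpc3, numbered 91 (6.77%, 5.49 to 8.25%). B-cell-like cells numbered 82 (6.10%), plasma-cell-like cells 24 (1.79%) and alveolar-macrophage-like cells 20 (1.49%). The markers fixed in advance gave no name to 4 clusters. Cluster 5 (91 cells) was led by the contractile genes Acta2, Tagln, Myl9 and Tpm2 together with Wif1. Cluster 8 (64 cells) was led by Mmp12, Ccl17, Tnip3, Ccl22 and Plbd1, and cluster 11 (48 cells) by Prg4, Alox15, Serpinb2, Saa3 and Fn1. Cluster 10 (48 cells) was led by the airway secretory genes Scgb1a1, Scgb3a2, Wfdc2 and Cyp2f2, the last 3 of which were detected in 27.1%, 35.4% and 33.3% of its cells.

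The libraries differed in composition. Endothelial-like cells made up 39.3% of library 1 (36.5 to 42.2%) and 77.4% of library 2 (70.9 to 83%). T-cell-like cells made up 13.1% of library 1 (11.2 to 15.2%) and 3.02% of library 2 (1.11 to 6.45%), and B-cell-like cells 7.07% (5.66 to 8.72%) and 0.503% (0.0127 to 2.77%). Cluster 5 accounted for 7.86% of library 1 (6.37 to 9.57%) and 1 cell of library 2. Interstitial-macrophage-like cells were at 8.82% (7.24 to 10.6%) and 7.54% (4.28 to 12.1%), intervals that overlapped. With 30 components fibroblast-like cells made up 1.86%, cluster 5 14%, cluster 10 1.26% and interstitial-macrophage-like cells, joined by cluster 8, 13% of all cells, so the division between fibroblast-like cells and cluster 5 depended on the clustering. These shares are shares of the cells that passed the mCherry gate and the authors' filters, not of the lung.

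The second question was where the transcripts of the reporter's own locus were found. Over both libraries Cdkn2a was highest in endothelial-like cells, where 328 of 604 cells had at least 1 UMI (54.3%, 50.2 to 58.3%) and the rate was 2.56 UMIs per 10000 (2.40 to 2.73). Cluster 11 came next, with 24 of 48 cells (50%, 35.2 to 64.8%) and 1.79 per 10000 (1.45 to 2.18). In library 1, which held 47 of the 48 cells of cluster 11, the order by share was the other way, with 51.1% (36.1 to 65.9%) in cluster 11 and 46.7% (42.0 to 51.4%) in endothelial-like cells. The rates there overlapped, at 1.85 (1.5 to 2.26) and 2.13 (1.95 to 2.31), and the thinned shares were 21.6% and 31.9%. Cluster 11 over both libraries was at 1.47 (1.16 to 1.84) without its 1 cell with most Cdkn2a UMIs. B-cell-like cells (26 of 82, 31.7%, 21.9 to 42.9%) and interstitial-macrophage-like cells (26 of 116, 22.4%, 15.2 to 31.1%) were intermediate, at 0.794 per 10000 (0.585 to 1.05) and 0.849 per 10000 (0.661 to 1.07). In the interstitial-macrophage-like class 1 cell supplied 34 of the 69 Cdkn2a UMIs, and the rate without it was 0.437 per 10000 (0.304 to 0.607). T-cell-like cells had Cdkn2a in 7.05% of cells (3.57 to 12.3%), fibroblast-like cells in 7.69% (3.15 to 15.2%) and cluster 5 in 4.40% (1.21 to 10.9%), with rates of 0.230, 0.204 and 0.264 per 10000. Without the 1 cell with most Cdkn2a UMIs, the rate was 0.117 in fibroblast-like cells (0.121 in library 1 alone), 0.135 in cluster 5, 0.0747 in place of 0.141 in plasma-cell-like cells and 0.148 in place of 0.272 in alveolar-macrophage-like cells. Depth differed between classes, from a median of 3605 UMIs per cell in T-cell-like cells through 5240.5 in endothelial-like cells and 10686.5 in cluster 11 to 30153.5 in plasma-cell-like cells. With each cell thinned to 2500 UMIs, which left out no cell, the share with Cdkn2a was 36.1% in endothelial-like cells, 21.1% in cluster 11, 15.1% in B-cell-like cells, 10.5% in interstitial-macrophage-like cells and 5.22% in T-cell-like cells. The remaining 6 classes lay between 1.83% and 3.88% after thinning.

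**Figure D1:**
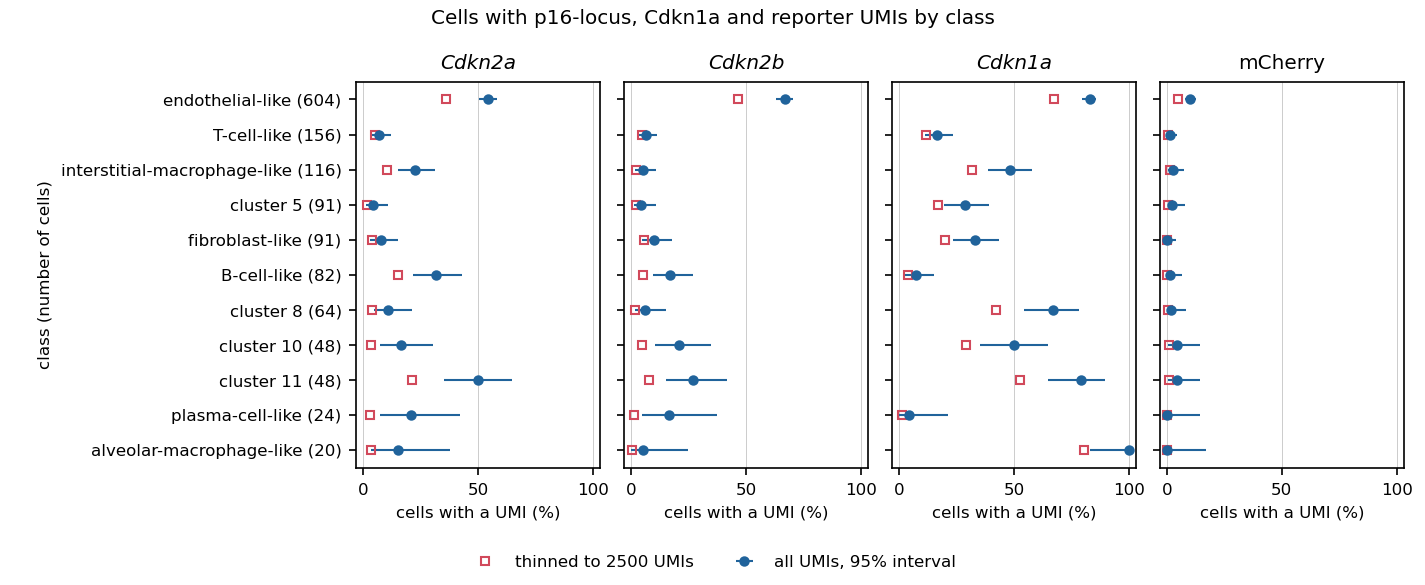
Share of cells with at least 1 UMI (x axis, percent) of Cdkn2a, Cdkn2b, Cdkn1a and mCherry in the 11 classes (y axis, number of cells in parentheses); filled points show all UMIs with 95% exact binomial intervals and open squares the expected share after thinning each cell to 2500 UMIs. Over both libraries endothelial-like cells are highest for Cdkn2b (66.9%) and mCherry (9.93%) and, at 54.3% beside 50% in cluster 11, for Cdkn2a. That order turns in library 1 (46.7% and 51.1%), though not after thinning there (31.9% and 21.6%).

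No class is known to lack Cdkn2a, so the low classes give the lowest rates seen and not a known background. In plasma-cell-like cells 5 genes, led by Igkc, took 65.9% of the UMIs, which lowers the rates and thinned shares of all other genes. Cdkn2a had a UMI in 5 of these 24 cells (20.8%, 7.13 to 42.2%), at a median depth of 30153.5 UMIs. Rates in T-cell-like, fibroblast-like and plasma-cell-like cells were 8.99% (4.91 to 15.1%), 7.96% (4.35 to 13.3%) and 5.51% (2.64 to 10.1%) of the endothelial-like rate over both libraries, the last 2 being 4.57% and 2.91% without 1 cell each. The 13 endothelial marker genes with at least 1 UMI per 10000 in endothelial-like cells had median rates of 0.236%, 0.451% and 0% of their endothelial-like level in those classes. Their highest values, 2.87% (Pecam1), 4.03% (Plvap) and 0.149% (Pecam1), lay below the Cdkn2a intervals, so even these classes need not show free RNA alone. Without 1 cell the fibroblast-like Cdkn2a interval (1.97 to 9.01%) reached Plvap. Markers came closer in clusters 10 and 5. Their medians were 3.01% and 3.31% there, beside Cdkn2a at 6.03% and 10.3%, or 4.48% and 5.27% without 1 cell. Free RNA of 1 gene differed between the libraries: Scgb1a1, the secretoglobin of club cells, had a UMI in 60.4% of endothelial-like cells of library 1 (55.8 to 65%) at 1.83 per 10000 and in 9.09% of those of library 2 (5.06 to 14.8%) at 0.216 per 10000. In cluster 10 its rate was 2582 per 10000, and 8 of the 48 cells held 93% of those UMIs. Cluster 10 had 46 cells in library 1 and 2 in library 2. Free RNA from other cells was not compared between the libraries.

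The neighbouring gene Cdkn2b, which encodes the related inhibitor p15, followed Cdkn2a in endothelial-like cells. Cdkn2b was detected in 66.9% of them (63.0 to 70.6%) at 2.88 UMIs per 10000 (2.71 to 3.06), against 0.190 per 10000 (0.157 to 0.227) in all other cells together. In cluster 11 it was at 0.351 per 10000 (0.211 to 0.548) and in B-cell-like cells at 0.248 (0.139 to 0.409), so these classes had less Cdkn2b than Cdkn2a. Cdkn1a, the p53-induced inhibitor p21, was detected in 82.9% of endothelial-like cells (79.7 to 85.9%) at 8.25 per 10000 (7.95 to 8.55). Its rate was higher in alveolar-macrophage-like cells, at 11.6 per 10000 (10.3 to 13.2) with UMIs in 20 of 20 cells, and low in B-cell-like cells, at 0.215 (0.115 to 0.368) with 6 of 82 cells, or 0.0840 (0.0273 to 0.196) without 1 of them. In the mm10 genome, whose coordinates are those of GRCm38, Cdkn2a lies on the minus strand of chromosome 4 from 89274471 to 89294653, Cdkn2b on the same strand from 89306299 to 89311039, and Cdkn1a on the plus strand of chromosome 17 from 29090976 to 29100727. Cdkn2a also encodes p19Arf, which shares the last exons, and 3' tags do not separate the transcripts of the gene.

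mCherry transcript was sparse in cells sorted for the protein. It was found in 73 of 1344 cells (5.43%, 4.28 to 6.78%), of which 60 were endothelial-like (9.93% of that class, 7.67 to 12.6%). The endothelial-like rate was 0.193 UMIs per 10000 (0.150 to 0.245) and that of the other cells together 0.0308 (0.0185 to 0.0481). By library the endothelial-like rate was 0.228 (0.173 to 0.295) in library 1 and 0.113 (0.0582 to 0.197) in library 2, the opposite order to Cdkn2a but with overlapping intervals. Fibroblast-like cells had mCherry in 0 of 91 cells, which allows a share of up to 3.30% of cells with a UMI, plasma-cell-like cells in 0 of 24 (up to 12.5%) and alveolar-macrophage-like cells in 0 of 20 (up to 15%).

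Cdkn2a also varied among the endothelial-like clusters. The rate was 3.14 UMIs per 10000 (2.91 to 3.40) in cluster 1 and 3.30 (2.75 to 3.92) in cluster 9, against 1.28 (1.08 to 1.51) in cluster 3. After thinning, the share with Cdkn2a was 42.6%, 37.8% and 17.5%. Cdkn1a showed the same order of high and low clusters, at 9.99 (9.56 to 10.4) and 9.18 (8.25 to 10.2) against 4.84 (4.45 to 5.26), as did Cdkn2b, at 3.72 (3.46 to 4) and 3.69 (3.1 to 4.35) against 1.11 (0.923 to 1.32). Within the libraries, cluster 1 had more Cdkn2a than cluster 3 in both, with 2.59 (2.32 to 2.88) against 1.20 (0.992 to 1.45) in library 1 and 4.18 (3.72 to 4.69) against 1.64 (1.14 to 2.29) in library 2. Over the whole class Cdkn2a was detected in 46.7% of library 1 cells (42.0 to 51.4%; thinned 31.9%) and 76.6% of library 2 cells (69.1 to 83.1%; thinned 48.4%).

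**Figure D2:**
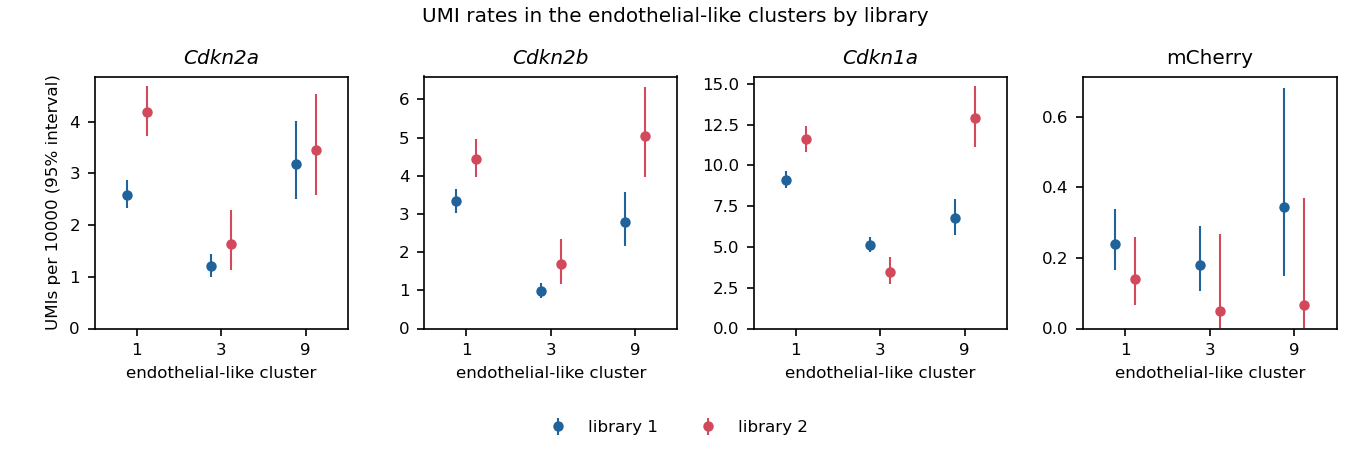
UMIs per 10000 (y axis, a separate scale per gene, from 0) of Cdkn2a, Cdkn2b, Cdkn1a and mCherry in endothelial-like clusters 1, 3 and 9 (x axis), with points for library 1 and library 2 and 95% Poisson intervals as bars. Cluster 3 has the lowest Cdkn2a in each library, at 1.20 and 1.64, and mCherry rests on few UMIs throughout.

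The third question was which functional genes set the classes apart. Each of 10 gene lists fixed in advance was compared between a class and the mean of the other classes, and its median difference was placed among 10000 random lists of like expression. These percentiles describe this table and are not tests. Of 110 pairs of class and list, 56 lay outside the range that held the central 95% of random lists, called the central range below. Rates below are UMIs per 10000 in the class against all remaining cells.

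In endothelial-like cells, senescence regulators as a list were near the middle of the random lists, at percentile 48.9 with 9 of 16 members higher. Cdkn1a (8.25 against 2.17), Cdkn2b, Cdkn2a (2.56 against 0.481) and Hmgb1 (6.33, 6.07 to 6.60, against 3.92, 3.77 to 4.08) were the members that differed most. Targets of p53 had 14 of 20 members higher and percentile 97.0. Phlda3, a p53-induced repressor of Akt signalling, was at 6.71 (6.45 to 6.99) against 0.614 (0.554 to 0.679), and the death receptor gene Fas at 2.02 (1.88 to 2.17) against 0.300 (0.258 to 0.346), while Btg2 was lower, at 2.94 (2.76 to 3.12) against 6.16 (5.96 to 6.35). Secretory factors linked to senescence were lower as a list by their median (-0.18), with 10 of 39 members higher and percentile 0, while their mean difference was -0.03. The members that were higher included Igfbp7 (80.6, 79.6 to 81.5, against 10.2, 9.99 to 10.5), the adhesion receptor gene Icam1 (5.85, 5.60 to 6.10, against 1.23, 1.14 to 1.32) and the protease inhibitor gene Timp2 (9.40 against 6.54), and Ccl6 was lower (0.0140 against 3.99). That low percentile was not particular to these cells. The secretory list was at 0.06 or below in T-cell-like, B-cell-like, plasma-cell-like, fibroblast-like and alveolar-macrophage-like cells and in cluster 5 too. Il6 UMIs were found in 0 of 604 endothelial-like cells, which allows up to 0.497% of cells with a UMI at this depth, and Il1b UMIs in 2.

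Among the other lists, genes of the interferon response had 11 of 17 members higher in endothelial-like cells and percentile 99.4, with Bst2 (tetherin) at 7.53 (7.25 to 7.82) against 1.78 (1.67 to 1.88). The percentile was 91.6 and 56.6 when means of linear values were compared with pseudocounts of 0.1 and 1. Lipid-handling genes had 4 of 16 members higher and percentile 0.02. T-cell-like, B-cell-like and fibroblast-like cells and clusters 5 and 10 were also at 0.02 or below for this list. The fatty acid receptor gene Cd36 was nevertheless higher in endothelial-like cells, at 22.8 (22.4 to 23.3) against 1.44 (1.35 to 1.54). Genes of the dissociation and stress response had 3 of 18 members higher and percentile 1, with Jun higher (23.5 against 12) and Hspa1a (1.18 against 9.64) and Fos (4.48 against 13.3) lower. Lysosomal genes had 8 of 25 members higher and percentile 4.33. Iron and oxidative stress genes had 7 of 15 members higher and percentile 13.8, with Mt1 and Fth1 lower (0.0224 against 12.6 and 20.4 against 65.6). Antigen presentation had 8 of 15 members higher and percentile 76.3. Its median difference was positive (0.06 on the natural-log scale) and its mean negative (-0.15), since the class I gene H2-D1 was higher (36.1 against 13.7) and Cd74 and other class II genes were lower (3.14 against 81.6 for Cd74). Proliferation genes were at percentile 66.2 with 8 of 13 detected members higher, among them Stmn1 (2.81, 2.64 to 2.99, against 0.259, 0.221 to 0.303). Mki67, a marker of cycling cells, had UMIs in 0 of 604 endothelial-like cells (up to 0.497% with a UMI) and in 22 of all 1344 cells. In library 1 alone, secretory factors, interferon response, lipid handling and stress response lay on the same sides, at percentiles 0, 99.3, 0.04 and 0.65. Alveolar-macrophage-like cells, with 18 cells there, fell below the minimum of 20 cells set for a class and were not among the other classes. Library 2 held too few cells of the other classes for this comparison.

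**Figure D3:**
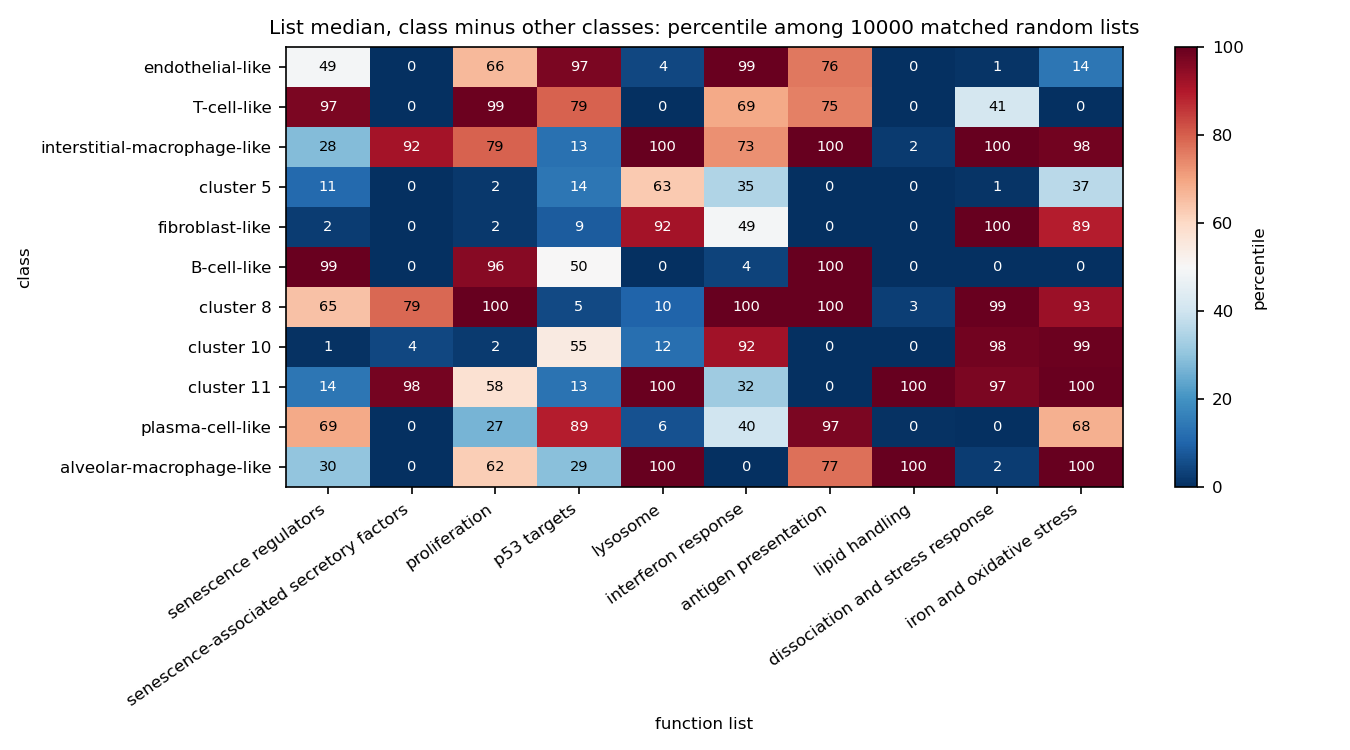
Percentile (colour and number, 0 to 100, rounded) of each function list's median difference between a class and the mean of the other classes among 10000 random lists matched on expression; rows are the 11 classes and columns the 10 lists. Secretory factors stand at percentile 0 in endothelial-like, T-cell-like, B-cell-like, plasma-cell-like and alveolar-macrophage-like cells and at 97.8 in cluster 11. Lysosomal genes stand at 100 in both macrophage-like classes.

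The secretory genes Il6, Il1b and Ccl8 were found mainly in other classes. Cluster 11 had Il6 in 18 of 48 cells (37.5%, 24.0 to 52.6%) at 1.46 per 10000 (1.15 to 1.82), ahead of fibroblast-like cells with 11 of 91 (12.1%, 6.19 to 20.6%) at 0.582 (0.416 to 0.793), or 0.368 (0.238 to 0.543) without 1 cell. It also had the highest rates of fibronectin, Fn1, at 97.3 (94.7 to 100) against 1.23 (1.16 to 1.30), and of the chemokine gene Cxcl2, at 53 (51.1 to 55.0) against 3.94 (3.81 to 4.07). In cluster 11 the secretory list had 22 of 39 members higher and percentile 97.8, lipid handling 11 of 16 higher and percentile 99.97, and antigen presentation 3 of 15 higher and percentile 0.01, with Cd74 at 0.794 (0.575 to 1.07), or 0.395 without 1 cell, against 55.9 (55.4 to 56.4). Il1b was highest in cluster 8, in 36 of 64 cells (56.2%, 43.3 to 68.6%) at 12.6 per 10000 (11.8 to 13.5). Of its UMIs most came from the 11 cells of library 2, and the rate in library 1 was 5.83 (5.21 to 6.51), in 27 of 53 cells. In cluster 8 antigen presentation had 14 of 15 members higher and percentile 100, Cd74 being at 350.2 against 30.9. Mki67 was found in 6 of the 64 cells of cluster 8 (9.38%, 3.52 to 19.3%; thinned 3.59%) and in 3 of its 53 cells of library 1 (5.66%, 1.18 to 15.7%).

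Interstitial-macrophage-like cells were high in lysosomal genes, with 22 of 25 members higher and percentile 100, among them Ctsb (32.0 against 3.81) and Ctss (15 against 3.30). Antigen presentation (11 of 15 higher, percentile 99.8), stress response (18 of 18, percentile 100) and iron and oxidative stress (10 of 15, percentile 98.4) were high too. The chemokine genes Ccl8 (21.2, 20.2 to 22.2, against 0.0515, 0.0377 to 0.0687), Ccl7 (11.9 against 0.208) and Ccl2 (11.5 against 0.923) were higher, and the secretory list as a whole was at percentile 91.6 with 20 of 39 members higher. Lipid handling was at percentile 2.32 with a median difference of -0.10, although its mean was 0.23, with Apoe at 223 (219 to 226) against 11.6. That percentile was 97.3 with a pseudocount of 0.1 on linear means and 88.0 in library 1 alone. In library 1 the other classes did not include alveolar-macrophage-like cells, a class high in this list, so the reference differed too.

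In the 20 alveolar-macrophage-like cells, lipid handling had 14 of 16 members higher and percentile 100, with the lipoprotein lipase gene Lpl at 24.8 (22.7 to 26.9) against 1.09 and Abcg1 at 14.9 (13.3 to 16.6) against 0.446. Lysosomal genes were at percentile 100 with 22 of 25 higher. Ccl6 was at 45.9 (43.1 to 48.8) against 1.53 (1.45 to 1.61). The secretory list was at percentile 0 by its median (-0.11) with 12 of 39 members higher, while its mean was 0.00 and positive.

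In fibroblast-like cells Igfbp6 (21.3 against 2.78), Igfbp4 (23.8 against 2.65) and Igfbp7 (45.5 against 35.3) were higher. In cluster 5 Igfbp6 (28.5 against 2.46), Igfbp4 (17.6 against 3.25) and Mmp2 (6.65 against 0.389) were higher. The secretory list nevertheless had negative medians in both (-0.07 and -0.08, percentiles 0.06 and 0.01) with positive means (0.23 and 0.16), 18 and 14 of 39 members being higher. With a pseudocount of 0.1 on linear means the fibroblast-like percentile was 99.98. Stress-response genes were high in fibroblast-like cells (12 of 18, percentile 100), with Egr1 at 15.7 (14.8 to 16.7) against 3.21 and Fos at 27.2 (26.0 to 28.5) against 8.80, and low in cluster 5 (7 of 18, percentile 1.15), where Fos was nevertheless at 20.7 (19.6 to 21.9) against 9.39.

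Most secretory genes were lower in the lymphoid classes than in the mean of the other classes. None of 39 secretory members was higher in B-cell-like cells, 4 were higher in T-cell-like cells and 1 in plasma-cell-like cells, and each class was at percentile 0. Among the 4 was Ccl5, in T-cell-like cells at 40.6 (39.0 to 42.2) against 1.21 (1.14 to 1.28). In B-cell-like cells senescence regulators were at percentile 99.3 with 10 of 16 members higher. These included Bcl2 (3.06, 2.64 to 3.53, against 0.562, 0.514 to 0.612) and Hmgb2 (3.80 against 1.5, and 2.29 without 1 cell), while Cdkn1a was lower (0.215 against 4.68). That percentile is therefore not a score of senescence. In plasma-cell-like cells 5 genes, led by Igkc, took 65.9% of the UMIs, so the rates of other genes there are lowered by that share.

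The last question was whether endothelial-like cells with detected Cdkn2a differed from the rest of their class. Matched on genes detected per cell, 220 cells with Cdkn2a were compared with 220 cells without. The 20 genes that differed most on mean natural-log values comprised 14 higher and 6 lower in cells with Cdkn2a. Which genes differed most depended on the scale, since 3 of the 20 remained among the 20 with a pseudocount of 0.1 on linear means. Higher were Igfbp7, at 88.6 UMIs per 10000 (87.0 to 90.2) against 68.9 (67.4 to 70.3), the carbonic anhydrase gene Car4, at 30.9 (30 to 31.9) against 21.3 (20.5 to 22.1), Emp2 (50.3 against 39.6), the endothelin receptor gene Ednrb (16.7 against 12.7) and Kitl (16.7 against 12.5). Lower were the phosphatase gene Ptprb, at 4.66 (4.29 to 5.05) against 8.6 (8.09 to 9.13), Plvap, which encodes a protein of endothelial fenestrae, at 2.07 (1.82 to 2.33) against 5.66 (5.26 to 6.09), Tm4sf1 (2.73 against 6.37), Cd93 (1.88 against 4.51), Gpihbp1 (4.39 against 7.70) and Ifitm3 (8.62 against 16.6). Cdkn2b was at 3.25 (2.94 to 3.58) against 2.09 (1.84 to 2.35), Cdkn1a at 9.38 (8.85 to 9.92) against 6.46 (6.03 to 6.92) and mCherry at 0.282 (0.197 to 0.390) against 0.111 (0.0607 to 0.186). The sides differed in make-up: 172 of the cells with Cdkn2a and 126 of those without were of cluster 1, 29 and 75 of cluster 3, and 62 and 30 came from library 2.

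Matching within cluster and library as well left 193 cells a side and smaller differences. The natural-log difference was 0.22 in place of 0.86 for Igfbp7 and 0.22 in place of 0.75 for Car4, and the largest among the 20 genes was 0.22. Of the 20 genes, 19 kept their sign on natural-log means. Ifitm3 moved from -0.49 to 0.04, although its UMI rate was still lower in cells with Cdkn2a (10.97 against 12.8), and the rates of Chst1 were close (3.98 against 4.02). Cdkn1a changed less, with 0.25 in place of 0.31, at 8.59 against 6.46 per 10000. Cdkn2b went from 0.39 to 0.14 with overlapping rates of 2.86 (2.56 to 3.19) and 2.34 (2.06 to 2.63), and mCherry from 0.10 to 0.07 with overlapping rates of 0.290 (0.200 to 0.408) and 0.150 (0.0873 to 0.240).

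Among the lists, stress-response genes were lower in cells with Cdkn2a under both matchings, with 2 of 17 members higher at percentile 0 and, within cluster and library, 4 of 18 at percentile 0.27. Fos was at 3.40 (3.09 to 3.74) against 5.29 (4.90 to 5.71). Targets of p53 were higher under both (12 of 17 members each time, percentiles 99.3 and 99.6), as were secretory factors (10 of 13, percentile 100, and 8 of 11, percentile 98.3). Their median differences within cluster and library were small, at 0.04 and 0.05 on the natural-log scale. Il6 and Il1b were not among the secretory members used. The lists share members, Cdkn1a being a senescence regulator and a p53 target and Gdf15 a p53 target and a secretory factor. Senescence regulators other than Cdkn2a were at percentile 58.2 with 7 of 12 members higher, and at 99.99 with 10 of 12 within cluster and library. Antigen presentation was at percentile 0 with 3 of 14 members higher, Cd74 being at 2.18 against 4.48, and at 18.1 with 3 of 13 within cluster and library. The other 5 lists lay inside the central range under both matchings.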

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

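Library 1 alone, library 2 alone, thinning, leaving out cluster 10 and matching within cluster and library were chosen after seeing the data; the cause was not tested where a value moved, except where the sentence gives it. In each alternative clustering a cluster took the class that held most of its cells. Leiden resolution 1.0 gave the same 11 class shares, which a finer split of the same clusters gives under that rule, so it is no independent check. A filter of 500 genes per cell removed no cell, and the count of 56 list and class pairs ranged from 48 to 58. Shares of cells: with 30 components interstitial-macrophage-like cells made up 13%, cluster 5 14.0%, fibroblast-like cells 1.86%, cluster 10 1.26% and cluster 8, merged into another class, 0%; with the function lists kept among the variable genes cluster 5 made up 13.8%, fibroblast-like cells 2.01% and cluster 10 1.26%. Endothelial-like cells made up 39.3% of library 1 and 77.4% of library 2, and in library 2 T-cell-like cells made up 3.02%, fibroblast-like cells 1.51%, cluster 10 1.01%, and cluster 5, B-cell-like cells and cluster 11 0.503% each. Share with Cdkn2a: among cells above the median of genes detected it was 64.1% in endothelial-like and 44.8% in B-cell-like cells; in endothelial-like cells it was 46.7% in library 1 and 76.6% in library 2. Thinning, which lowers detection by construction, gave 36.1% in endothelial-like cells, 10.5% in interstitial-macrophage-like cells, 15.1% in B-cell-like cells, 3.88% in cluster 8, 3.47% in cluster 10, 21.1% in cluster 11 and 3.11% in plasma-cell-like cells. List percentiles in endothelial-like cells: p53 targets moved outside the central range with a pseudocount of 0.1 (98.0), with no filter on low genes (97.51) and without multi-lineage cells (97.54); lysosome moved outside it on the low side with a pseudocount of 0.1 (0.65) and without cluster 10 (1.90); interferon response moved inside with pseudocounts of 0.1 (91.6) and 1 (56.6). Sides were reversed for lipid handling in interstitial-macrophage-like cells (97.3 with a pseudocount of 0.1, 88.0 in library 1) and in cluster 10 (86 with that pseudocount) and for secretory factors in fibroblast-like cells (99.98 with it). Percentiles in library 1 leave out alveolar-macrophage-like cells, which had 18 cells there, below the minimum of 20 for a class. Not all 110 pairs of class and list were followed one by one, with 62 at resolution 1.0, where all kept their place. The counts that follow therefore do not show how often pairs inside the central range moved outside it. Of 422 percentiles followed, 384 kept their place inside or outside the central range, 29 moved inside it, 5 moved outside it and 4 changed direction. Of the 29, 9 did so with a pseudocount of 0.1 and 6 in library 1 alone. Apart from interferon response in endothelial-like cells, the 29 are not named here. Of the 20 genes of the Cdkn2a comparison, 3 remained among the 20 with a pseudocount of 0.1 on linear means, 4 when matched within cluster and library, 11 in library 2 and 17 to 20 under the other alternatives; 1 gene, Ifitm3, changed sign (a natural-log difference of 0.038 within cluster and library). No test paired by library was run between classes, since only endothelial-like cells reached the minimum of 20 cells set for a class in library 2. The Cdkn2a comparison could have been paired, with 2 pairs, and was not tested. Matched on genes detected, its 20 genes had the same sign in both libraries, although they were picked on both together. The matching within cluster and library took 25 cells of library 2 on each side. Each library alone stands for leaving out the other, and the planned replicate block and count model on recovered UMIs were not run. Depth limits rare transcripts, such as mCherry with 88 UMIs in all and Mki67 with 58.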

Other observations

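At a finer resolution 1 group of endothelial-like cells had little Cdkn2a. This group of 70 cells led by Vwf, Ptprb, Edn1, Plvap and Gja4, genes of larger vessels among them, had Cdkn2a in 6 cells (8.57%, 3.21 to 17.7%) at 0.687 UMIs per 10000 (0.460 to 0.986). A group of 75 cells led by Plvap, Kit, Sema3c, Ptprb and Gpihbp1 had Cdkn2a in 58.7% (46.7 to 69.9%) at 1.63 per 10000 (1.35 to 1.95). Median depth was 4196.5 and 9258 UMIs, and the thinned shares were 6.04% and 28.2%. The Cdkn2b rate was 0.213 (0.0974 to 0.404) and 1.63 (1.35 to 1.95) in these groups, whereas intervals overlapped for Cdkn1a, at 4.33 (3.73 to 5.01) and 5.14 (4.63 to 5.69), and for mCherry, at 0.0710 (0.0146 to 0.208) and 0.207 (0.116 to 0.342). The share of cells with Cdkn1a did differ, at 48.6% (36.4 to 60.8%) and 89.3% (80.1 to 95.3%), or 38.2% and 57.2% after thinning. The T-cell-like class parted into 80 cells led by Trdc, Il17a and Tcrg-C1, genes of gamma delta T cells, with Cdkn2a in 6.25% (2.06 to 14%), and 76 cells led by Ccl5, Nkg7 and Ms4a4b with Cdkn2a in 7.89% (2.95 to 16.4%).

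The tests on reporter transcript and on library 2 were chosen after the result was seen, and those on free RNA and joint capture were fixed before they were run. No biological explanation was tested for any pattern, since the labels give 1 group.

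Cdkn2a UMIs were found in B-cell-like cells, cluster 11 and interstitial-macrophage-like cells, and free RNA from endothelial-like cells was weighed first. The Cdkn2a rate was 31.0% (22.9 to 41.1%), 69.9% (56.7 to 85.3%) and 33.1% (25.8 to 41.9%) of the endothelial-like rate, whereas 13 endothelial markers had medians of 1.24%, 1.05% and 2.12%, which free RNA alone does not give. The highest marker was Pecam1 at 4.46% in B-cell-like cells and Ednrb at 54.9% in cluster 11 and 13.8% in interstitial-macrophage-like cells, and without 1 cell the Cdkn2a values of the last 2 classes were 57.6% (45.4 to 71.9%) and 17.0% (11.9 to 23.7%), intervals that reach Ednrb but no other marker. The interval of 11.9 to 23.7% also overlapped that of T-cell-like cells (8.99%, 4.91 to 15.1%), a low class that lay above its markers too. Joint capture with an endothelial cell was weighed next, and 3.85% (1 of 26, up to 19.6%), 0% (0 of 24, up to 12.5% by the limit of 3 counts and 14.2% by the exact interval) and 7.69% (2 of 26, up to 25.1%) of the cells with Cdkn2a carried 3 or more endothelial markers. By these measures neither explanation accounted for the values in full.

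mCherry UMIs were found in few of the sorted cells, and if capture of reporter RNA were low in all classes alike, mCherry would make up the same part of mCherry and Cdkn2a UMIs in each. This holds only if the p19Arf part of the Cdkn2a UMIs is alike in all classes, which 3' tags cannot show. Over both libraries it made up 6.01% (3.66 to 9.23%) outside the endothelial-like class and 7.02% (5.50 to 8.80%) inside. In library 1 it made up 6.23% (3.79 to 9.56%) outside and 9.68% (7.41 to 12.4%) inside, where the first interval misses the second value but both intervals overlap, which leaves this explanation open. Within the endothelial-like class the part was 3.05% (1.58 to 5.26%) in library 2, below library 1, so the part was not alike in both libraries. The rate outside was 0.0308 per 10000 (0.0185 to 0.0481) against 0.193, which cells without the reporter in the gate could give, but so could a lower p16 level, and these values cannot tell them apart.

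Endothelial-like cells of library 2 had Cdkn2a more often. Depth does not raise a UMI rate, yet the rate was 3.59 (3.24 to 3.96) in library 2 and 2.13 (1.95 to 2.31) in library 1. Another mix of the 3 clusters is not the whole cause either, because with the clusters weighted as in library 1 the rate of library 2 was 3.16 (2.82 to 3.50). The rates in library 2 and library 1 were 4.18 (3.72 to 4.69) and 2.59 (2.32 to 2.88) in cluster 1, 3.46 (2.58 to 4.53) and 3.19 (2.51 to 4.01) in cluster 9, and 1.64 (1.14 to 2.29) and 1.20 (0.992 to 1.45) in cluster 3; these intervals cover counting error only, with 1 library on each side, and whether the clusters differ in this was not tested. A difference between animals or library preparations was not tested, and the mCherry rate of these cells was not higher in library 2, at 0.113 (0.0582 to 0.197) against 0.228 (0.173 to 0.295).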
